A study of Mus musculus with 13 samples.

How the data were processed

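RNA from cDC1 and cDC2 sorted from the colon lamina propria of mice on day 7 of 3.5% DSS was sequenced in 13 libraries, and per the labels these were made with the SMARTer Ultra Low Input RNA Kit V4. The sort took live CD45+ MHCII+ CD11c+ cells negative for F4/80, CD64, CD3, CD19, NK1.1 and CD138, with cDC1 as XCR1+ CD172a- and cDC2 as XCR1- CD172a+. F/F stands for Hamp-floxed animals and KO for Hamp-floxed animals with CD11c-Cre, as the labels give the genotypes; which exons are floxed is not given in the sources used here. The authors' table holds raw read counts per gene for 27179 NCBI Gene numbers, and the submitters' processing notes name CASAVA 1.8.2, STAR 2.3.0 and mm10; the counter and its annotation are not stated. The counts are whole numbers, 25275 gene numbers were matched to a symbol and position in the RefSeq annotation of the same assembly, and the 1904 others hold 0.434% of the counts.

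Libraries held 33692736 to 58835599 counts, so that 3 counts, the floor used here, are about 0.051 to 0.089 CPM, and depth limits the lowest transcripts. The spread between libraries was larger than counting noise, with chi-square per degree of freedom of 83.4 to 361 between libraries of the same group and a common biological coefficient of variation of 58.1%. Spearman correlations were 0.902 to 0.919 within groups and 0.885 to 0.902 between subsets. TMM factors and library composition were checked per library, and principal components used log2 CPM with a prior count of 2.

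Genes were kept by filterByExpr on the 4 groups (minimum count 10, CPM above 0.199, minimum total 15), which left 15899. All libraries entered 1 edgeR quasi-likelihood fit with 4 group means, TMM scaling and a shared estimate of the spread, in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The contrasts were KO against F/F in cDC1, in cDC2 and averaged over both, the difference between these genotype effects (cDC2 minus cDC1), and cDC2 against cDC1 in F/F and in KO. Genes with a Benjamini-Hochberg adjusted p under 0.05 count as changed, and every adjusted p of a gene is from edgeR unless another tool is named. Levels of Hamp and iron genes were also compared by 2-sided exact permutation. The p-values of single genes and of permutations measure only the spread between libraries, and the labels do not state whether each library is a separate animal.

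The lists cover iron handling, hepcidin-inducing signals, dendritic cell programmes and function, metabolism, stress and proliferation, and markers of other cells the gate could hold, 33 in all. They were tested with camera from limma at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. Camera sets the genes of a list against all other genes, so its p-values rest largely on the spread across genes. A very small camera p is therefore no measure of the spread between libraries. Members were counted over all genes and with p adjusted over the list alone. Genes are named by rule: the iron genes in every contrast, the 6 largest changes each way among genes that passed with at least 10 CPM and no overlap between groups, where fewer than 6 genes passed the 5 smallest p each way, and up to 4 members with the smallest p of each list that passed and of 8 lists fixed for every contrast. Groups, contrasts, tests, lists, naming rule and alternatives were fixed before the data were examined.

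On simulated data with the real library sizes and spread, 2-fold, 4-fold, 8-fold and 16-fold changes were recovered in 26, 74, 94 and 98% of genes for KO against F/F in cDC1, 16, 78, 92 and 98% in cDC2, 42, 86, 100 and 100% for the average, and 2, 42, 64 and 86% for the difference of effects. For cDC2 against cDC1 they were recovered in 34, 78, 92 and 94% in F/F and 12, 68, 88 and 96% in KO, and 3.4 to 5.1% of calls were false. Changes were placed only in genes with a mean above 100 expected counts per library. The shares therefore do not cover lower genes such as Slc40a1 and Hamp. Alternatives were RLE size factors, no filter, a filter of 10 CPM in 2 libraries, DESeq2, limma-voom with quality weights, only the libraries compared, replicate blocks, each library left out in turn, and for lists an estimated correlation and fry. The description's numbers, used for 1 of the blocks, conflict as animal numbers: 7 marks a KO library of cDC1 and an F/F library of cDC2, and 6 marks KO libraries of both subsets and 1 F/F library of cDC2. No library was left out of the main analysis, and exon-level reads were not analysed here.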

Results

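Type 1 and type 2 conventional dendritic cells (cDC1 and cDC2) sorted from the colon lamina propria of mice were compared between Hamp-floxed animals (F/F) and Hamp-floxed animals that also carry CD11c-Cre (KO), on day 7 of 3.5% DSS. The data are 13 RNA-seq libraries: 3 of cDC1 F/F, 3 of cDC1 KO, 5 of cDC2 F/F and 2 of cDC2 KO. Each has 33692736 to 58835599 counts and 17961 to 21644 genes with a count. Levels are CPM after TMM scaling, as mean ± SD over libraries. Log2 fold changes come with their standard error (SE), and positions are on mm10. The first principal component (37.9% of the variance) parts the cDC1 from the cDC2 libraries, and the second (8.42%) spreads mainly the cDC2 libraries.

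**Figure D1:**
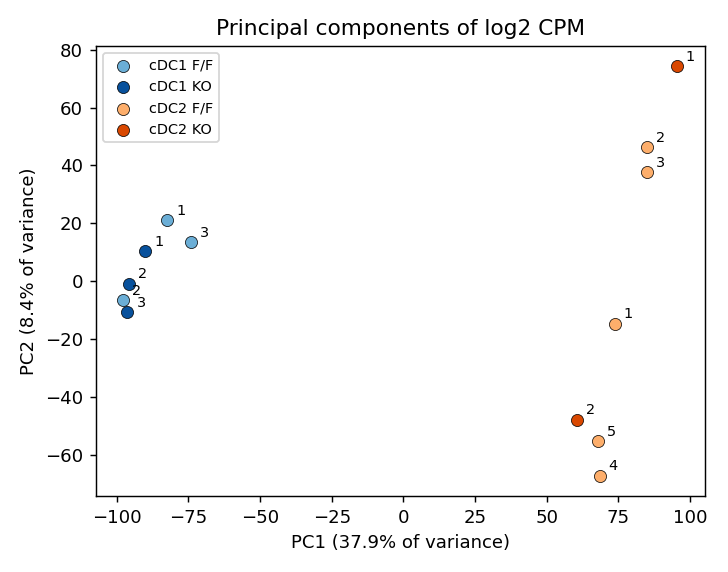
Principal components of log2 CPM over the tested genes. PC1 (37.9%) separates 6 cDC1 from 7 cDC2 libraries, and PC2 carries 8.42%. Numbers beside the points are replicate numbers.

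Hamp, the hormone hepcidin and the gene targeted here (chromosome 7, 30942368 to 30944029), had 0 counts in all 6 cDC1 libraries, F/F and KO alike. In cDC2 F/F it had 14, 6, 450, 0 and 5 counts in replicates 1 to 5, and in cDC2 KO 1 and 0. The mean was 2.11 ± 4.44 CPM in cDC2 F/F (n = 5) and 0.0126 ± 0.0179 in cDC2 KO (n = 2), with a 2-sided exact permutation p = 0.429. Without F/F replicate 3, at 10.04 CPM, the F/F mean was 0.124. Hamp2, a close paralog of Hamp, had counts of 20, 0 and 1 in cDC1 KO, 0 in each cDC1 F/F library, 0, 0, 1, 1 and 0 in cDC2 F/F, and 0 and 6 in cDC2 KO. Hamp thus had 14 counts or fewer in 12 of the 13 libraries, and the counts per gene do not tell which exons are present.

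Slc40a1 (ferroportin, the iron exporter that hepcidin binds; chromosome 1, 45908070 to 45926532) had 104, 62 and 142 counts in cDC1 F/F and 2, 2 and 2 in cDC1 KO. Its level was 2.06 ± 0.758 against 0.0428 ± 0.00152 CPM (n = 3 each). The ratio was 47.9 (95% counting interval 21.8 to 132), and the log2 fold change -5.51 (SE 1.11) had adjusted p = 0.418 over all genes in edgeR. The interval covers counting error only, not amplification or differences between libraries, and 2 counts per library lie under the floor of 3, so neither number is an exact size. The 2-sided exact permutation p = 0.1 is the smallest that 3 against 3 libraries can give. Among the 30 tested members of the iron handling list, Slc40a1 alone fell in cDC1 when p was adjusted over the list alone (adjusted p = 0.00589), and 0 of the 30 did over all genes. In cDC2 its levels were 2.06 ± 1.43 CPM in F/F and 1.31 ± 0.616 in KO, and the difference between the genotype effects was 4.85 (SE 1.33, adjusted p = 0.792). The ferritin heavy chain Fth1 was at 4586 ± 968 and 4960 ± 854 CPM in cDC1 F/F and KO and 11920 ± 2671 and 10770 ± 423 in cDC2. The light chain Ftl1 was at 553 ± 115 and 639 ± 127 in cDC1 and 383 ± 88.05 and 276 ± 1.48 in cDC2. Tfrc, the transferrin receptor for iron uptake, had log2 fold changes of -0.26 (SE 0.22, adjusted p = 1) in cDC1 and -0.29 (SE 0.23, adjusted p = 0.9696) in cDC2. The epithelial marker list was also lower in the same cDC1 KO libraries, at 76.5 ± 4.35 summed CPM against 525 ± 349 in cDC1 F/F. Replicate 2, with the fewest Slc40a1 counts of the F/F libraries, had the lowest epithelial sum of them (169).

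**Figure D2:**
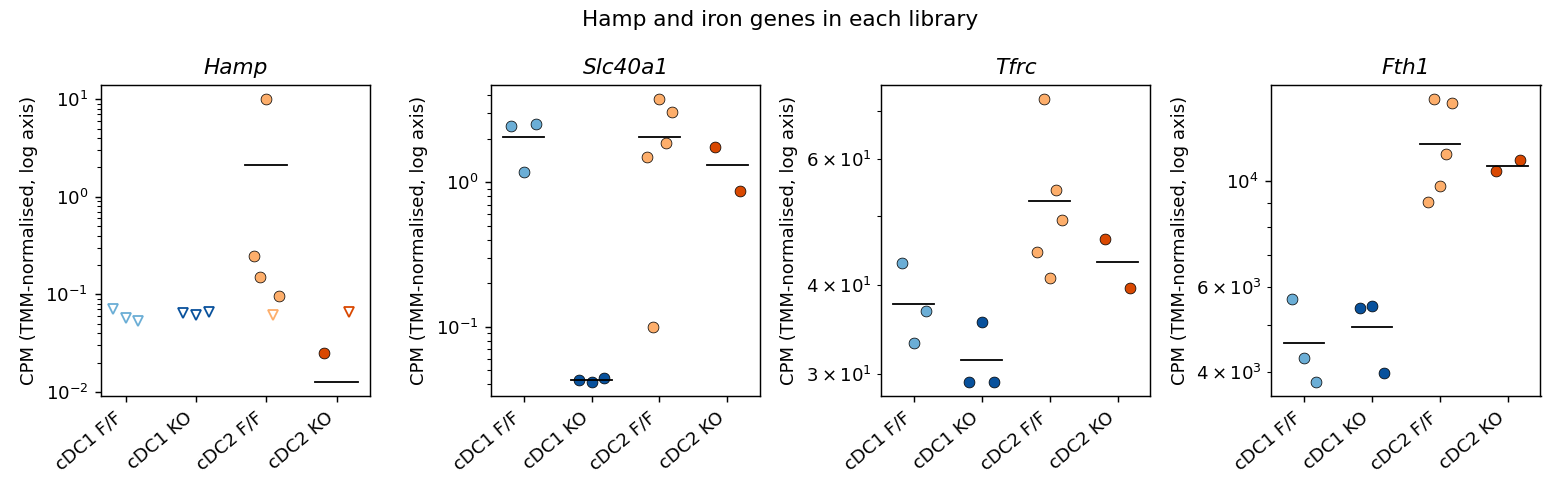
Hamp, Slc40a1, Tfrc and Fth1 in each library, with bars at group means. Open triangles mark the upper limit of libraries with 0 counts. Slc40a1 is at 2.06 ± 0.758 CPM in cDC1 F/F and 0.0428 ± 0.00152 in cDC1 KO, and Hamp reaches 10.04 CPM in 1 cDC2 F/F library.

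In cDC1, KO against F/F (n = 3 each), the gene that passed was Ehf, an ETS-family transcription factor of epithelia and dendritic cells (chromosome 2, 103263431 to 103303275). It is named here after its values were seen because it lies under the 10 CPM of the naming rule. Ehf fell from 6.91 ± 1.48 to 0.204 ± 0.227 CPM, a log2 fold change of -5.08 (SE 0.67, adjusted p = 0.0371). Its level was 9.75 ± 3.12 CPM in cDC2 F/F and 6.98 ± 2.65 in cDC2 KO. The epithelial marker sum was at 525 ± 349 and 76.5 ± 4.35 CPM in the same cDC1 libraries. Il1rn, the interleukin 1 receptor antagonist, was at 15.98 ± 2.61 and 4.82 ± 2.83 CPM in F/F and KO, log2 fold change -1.73 (SE 0.35, adjusted p = 0.418). Areg, an epidermal growth factor receptor ligand, was at 16.3 ± 9.16 and 4.94 ± 3.05. Osm, an interleukin 6 family cytokine, was at 3.39 ± 0.178 and 1.55 ± 0.728. Itgad, an integrin alpha chain, was at 2.999 ± 1.68 CPM in F/F and 12.6 ± 2.51 in KO, log2 fold change 2.08 (SE 0.37, adjusted p = 0.314). Itgam (CD11b) was at 2.24 ± 1.29 and 5.496 ± 0.826, and Cd7 at 11.8 ± 3.498 and 20.98 ± 4.12. The cDC1 core list, which holds the lineage factor Batf3 and the receptor Xcr1, had 0 of 25 members past the threshold and a median log2 fold change of 0.011. Batf3 had 0.25 (SE 0.27) and Wdfy4, needed for cross-presentation, -0.16 (SE 0.14). Adjusted over each list alone, Il1rn fell among 30 inflammatory cytokines, Areg among 22 mucosal tolerance genes and Clec4a2, an inhibitory lectin, among 25 cDC2 core genes (-2.67), while Itgam and Cd7 rose in that last list. Clec4e rose among 26 pattern recognition genes and 16 neutrophil markers (3.71), Areg fell among 15 NK and ILC markers, and of 18 plasmacytoid DC markers 3 fell and 1 rose. Over all genes 0 of these members passed.

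By edgeR 1 gene passed in cDC1 (0 higher, 1 lower), with 646 at an unadjusted p under 0.05 where 795 fall by chance among 15899 genes. Limma-voom called 1 and DESeq2 113 (16 higher, 97 lower), 70 of them with a mean under 10 CPM in every group and 7 in the epithelial list. Groups of 3 against 3 did not overlap in 8.99% of genes, and chance gives 10%. The Ehf call ended without cDC1 F/F replicate 1 or 3 or KO replicate 1 or 2 (0 genes each), with only the cDC1 libraries fitted and with a block by the title's replicate number (smallest adjusted p = 0.219 and 0.104). Without F/F replicate 2 the count was 5: Ehf, Cela1, Epcam, Hbegf and Clec4a2.

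All 27 tested epithelial markers had negative log2 fold changes in cDC1 KO against F/F (median -3.38), and 14 of them fell when adjusted over the list alone, 0 over all genes. Lgals4, an intestinal galectin, was at 112 ± 86.3 CPM in F/F and 4.58 ± 1.49 in KO. Krt8, an epithelial keratin, was at 26.7 ± 23.6 and 0.905 ± 0.344, and Guca2a (guanylin) at 12.8 ± 5.74 and 0.905 ± 0.664. Outside the list, Muc13, a membrane mucin, was at 16.9 ± 14 and 0.188 ± 0.1298 CPM, and Cela1, an elastase, at 11.5 ± 14.2 and 0.116 ± 0.111. The epithelial sum was 540.4, 169 and 866 CPM in F/F replicates 1 to 3 and 81.2, 75.5 and 72.7 in KO. The list passed camera (adjusted p = 4.47e-21), with adjusted p = 0.0696 with an estimated correlation, and its median was -1.77 without F/F replicate 3 and -0.41 (adjusted p = 0.116) without F/F replicates 1 and 3. Cholesterol synthesis had all 21 members negative (median -0.41, adjusted p = 9.52e-06, and adjusted p = 0.296 with an estimated correlation) and 0 past the threshold. Sqle, which makes squalene epoxide, had -0.64 (SE 0.2999), Cyp51 -0.41 (SE 0.199), Hmgcs1 -0.47 (SE 0.24) and Idi1 -0.73 (SE 0.395). The cholesterol median was -0.26 without F/F replicate 2 and -0.38 (adjusted p = 4.33e-05) without F/F replicates 1 and 3. Oxidative phosphorylation genes had a positive log2 fold change in 83 of 94 (median 0.15, camera adjusted p = 2.22e-05, and adjusted p = 0.752 with an estimated correlation). This call ended without F/F replicate 2 (median 0.058), and the median was 0.302 without F/F replicate 1, 0.087 without KO replicate 1, 0.25 without KO replicate 3 and 0.38 (adjusted p = 2.25e-09) without F/F replicates 1 and 3. B and plasma cell markers had a median of 0.79 (camera adjusted p = 2.22e-05, and adjusted p = 0.296 with an estimated correlation). In 1 library, KO replicate 3, they summed to 3919.6 CPM, against 433 to 604 in the other 5 cDC1 libraries, and Igkc stood at 1895 CPM. Without it the median was 0.016 and the call ended, and without F/F replicate 3 the median was 1.33. Smaller shifts passed camera in 4 lists, each with adjusted p = 0.752 with an estimated correlation and each lost without several single libraries and with the mitochondrial rRNA share as a covariate. Iron-sulfur and heme synthesis had a median of 0.13 (adjusted p = 0.0466; 0.089 to 0.18 over the left-out libraries, lost without F/F replicate 2 or 3 or KO replicate 1 or 2). The unfolded protein response had 0.099 (adjusted p = 0.0466; 0.0054 to 0.23, lost without F/F replicate 1 or 3 or KO replicate 2 or 3), with Manf, a secreted stress factor, at 0.36 (SE 0.18). Cell cycle genes, with Ube2c at 0.91 (SE 0.46), had 0.12 (adjusted p = 0.0477; 0.023 to 0.27, lost without F/F replicate 1 or 2 or KO replicate 2 or 3). Macrophage markers, with C1qc, a complement chain, at -1.45 (SE 0.46), had -0.36 (adjusted p = 0.0466; -0.42 to -0.024, lost without F/F replicate 1 or KO replicate 1 or 2).

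In cDC2, KO (n = 2) against F/F (n = 5), Fam149a (chromosome 8, 45336715 to 45382291) rose from 6.45 ± 0.545 to 17.1 ± 0.806 CPM. Its log2 fold change was 1.41 (SE 0.17, adjusted p = 0.00909). In cDC1 it was at 89.9 ± 9.09 CPM in F/F and 85.3 ± 8.02 in KO, and the difference between the subsets' genotype effects was 1.48 (SE 0.24, adjusted p = 0.322). Plcb4 and Plcb1, phospholipase C beta enzymes, were at 2.28 ± 1.08 and 0.653 ± 0.588 CPM in F/F and 10.8 ± 2.095 and 18.7 ± 7.39 in KO. Their log2 fold changes were 2.24 (SE 0.36, adjusted p = 0.1101) and 4.83 (SE 0.97, adjusted p = 0.375). On the negative side were Ints13, an Integrator subunit, -1.57 (SE 0.34, adjusted p = 0.379), the small GTPase Rab33b -1.17 (SE 0.27), Tcta -1.26 (SE 0.303), the palmitoyltransferase Zdhhc6 -0.97 (SE 0.24) and Zfp84 -0.77 (SE 0.21). Inflammatory cytokine genes had 0 of 30 members past the threshold (median -0.076), with Il6 at 46.7 ± 19.7 CPM in F/F and 26.2 ± 7.75 in KO and Tnf at 57.1 ± 9.01 and 46.03 ± 2.63. Of the iron handling genes, with 0 of 30 past the threshold, Slc39a8, a metal importer, was at 1.68 ± 0.9798 and 9.72 ± 9.89 CPM and Hmox1, which breaks down heme, at 15.4 ± 10.1 and 5.74 ± 2.87. The cDC2 core list had a median of -0.15 with 0 of 25 past the threshold: Cd209a, the mouse DC-SIGN, was at 1257 ± 426 and 769 ± 252 CPM and Notch2 at 27.8 ± 5.19 and 40.6 ± 2.38.

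By edgeR 1 gene passed in cDC2 (1 higher, 0 lower), with 863 at an unadjusted p under 0.05. Limma-voom called 0 and DESeq2 128 (36 higher, 92 lower), 91 of these with a mean under 10 CPM in every group. Groups did not overlap in 7.43% of genes, and chance gives 9.52%. Fam149a passed without each cDC2 F/F library in turn, and its log2 fold change was 1.45 without KO replicate 1 and 1.34 without KO replicate 2. It was not called by limma-voom (adjusted p = 0.549) or with a block by the title's replicate number (log2 fold change 1.47, adjusted p = 0.885). With the cDC2 libraries fitted alone it had 1.41 (adjusted p = 0.9996). The call thus depends on the spread shared with the cDC1 libraries, none of which was left out for this comparison. The count was 2 without F/F replicate 3, 6 without KO replicate 1 and 7 without KO replicate 2.

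Maturation and migration genes had negative log2 fold changes in 23 of 29 in cDC2 KO (median -0.24, camera adjusted p = 0.0384, and adjusted p = 0.577 with an estimated correlation). Cd40, a costimulatory receptor, had -0.43 (SE 0.25) and Nudt17 -0.75 (SE 0.41), and the call ended without F/F replicate 1 or 5 or KO replicate 1 (median -0.41 to -0.12 over the left-out libraries). Cell cycle genes had a median of -0.298 (camera adjusted p = 0.0384, and adjusted p = 0.596 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit, was at 21.99 ± 8.59 and 8.65 ± 5.54 CPM. This call ended without F/F replicate 1, 2 or 5 or KO replicate 1 or 2 (median -0.47 to -0.16). Ribosomal protein genes had a median of 0.26 (camera adjusted p = 1.84e-04, and adjusted p = 0.715 with an estimated correlation), which turned to -0.049 without KO replicate 1 and was 0.42 without KO replicate 2 and 0.17 without F/F replicate 4. Their sum was 14707 and 10472 CPM in KO replicates 1 and 2 and 9448, 14013, 11618, 9036 and 11099 in F/F replicates 1 to 5. The mitochondrial rRNA share was 3.71% and 0.596% in these KO libraries and 1.27%, 2.74%, 2.12%, 0.44% and 0.409% in F/F (Spearman correlation 0.75 over the 7 libraries). With that share as a covariate the ribosomal median was 0.11 (adjusted p = 0.0117). Marker lists of other cells had medians of both signs. B and plasma cell markers had a median of -1.26 (camera adjusted p = 1.59e-05, and adjusted p = 0.161 with an estimated correlation). They summed to 8435 ± 4924 CPM in F/F and 2743 ± 2712 in KO, and the median was -2.54 without KO replicate 1. T cell markers had a median of -0.77 (adjusted p = 0.00176, and adjusted p = 0.564 with an estimated correlation), a call that ended without KO replicate 2 (median -0.51). Without F/F replicate 4 the median was -0.44. Neutrophil markers had a median of 1.07 (adjusted p = 6.82e-05, and adjusted p = 0.0778 with an estimated correlation). Retnlg was at 0.0912 ± 0.0584 and 6.8 ± 9.12 CPM (it and 1 more of 16 rose over the list alone) and the sum at 81.8 ± 17.9 in F/F and 129.9 ± 9.62 in KO, and the median was 0.59 without KO replicate 2. Erythroid markers stood at 95.6 CPM in KO replicate 2 and at most 2 in each other library. Hbb-b1, adult beta globin, was at 38.5 CPM there, and both tested members gave a median of 7.32 (adjusted p = 6.38e-05, and adjusted p = 0.0863 with an estimated correlation), or 4.71 without that library. Macrophage markers, with Lyz2 at 3273 ± 1166 and 1868 ± 320.3 CPM and Cd14 at 199.5 ± 77.9 and 108 ± 25.8, had a median of -0.39 (adjusted p = 0.0271, and adjusted p = 0.564 with an estimated correlation). This was lost without F/F replicate 5 or KO replicate 2 (median -0.18 without KO replicate 2 and -0.79 without KO replicate 1). Epithelial markers had a median of -1.02 (adjusted p = 0.00796, and adjusted p = 0.564 with an estimated correlation), with Car2, a carbonic anhydrase of colonocytes, at 184 ± 61.6 and 91.2 ± 7.29 CPM. Stromal markers had one of -1.83 (adjusted p = 0.0384, and adjusted p = 0.564 with an estimated correlation). Their sum, by contrast, was 1183 ± 208 CPM in F/F and 1139 ± 27.8 in KO. The epithelial call was lost without KO replicate 1, and its median was -3.01 without KO replicate 2. The stromal call was lost without F/F replicate 1 (median -0.77) or 4 or either KO library, and with the mitochondrial rRNA share as a covariate (-1.85, adjusted p = 0.0864).

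**Figure D3:**
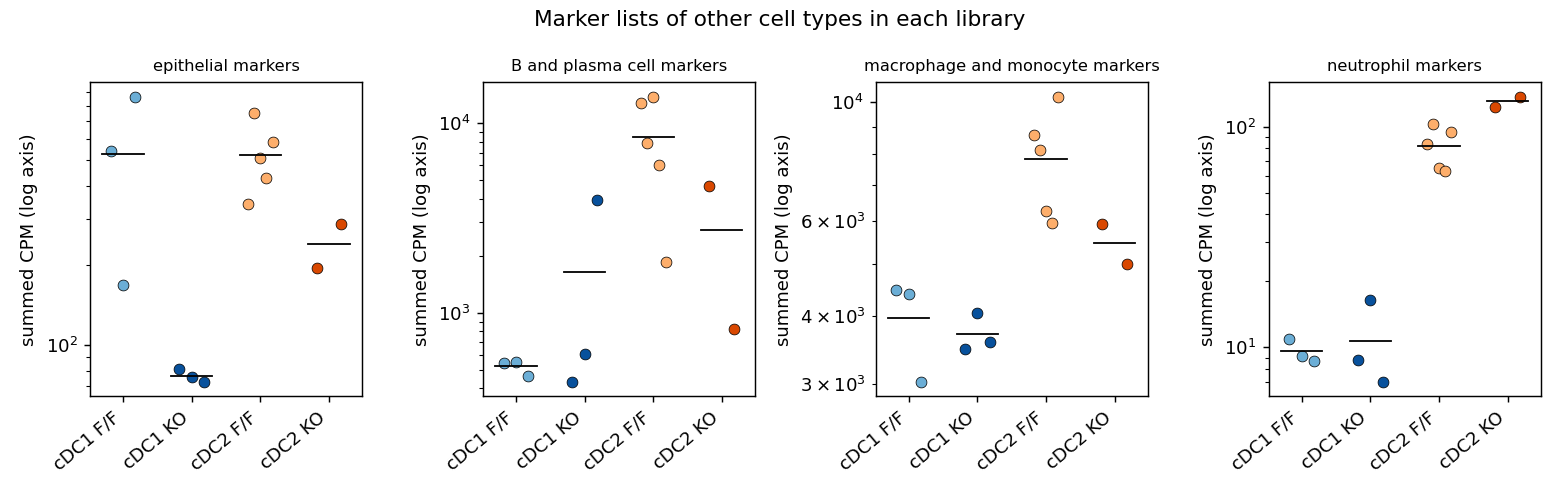
Summed CPM of marker lists of other cell types in each library, with bars at group means. The epithelial sum is 525 ± 349 CPM in cDC1 F/F and 76.5 ± 4.35 in cDC1 KO. The B and plasma cell sum reaches 3919.6 in 1 cDC1 KO library.

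Averaged over both subsets, KO (5 libraries) against F/F (8), Itgad had the smallest p: 1.81 (SE 0.25, adjusted p = 0.0648). In cDC2 its level was 6.35 ± 0.6004 CPM in F/F and 18.5 ± 1.24 in KO. It lies next to Itgax, the CD11c gene whose promoter drives the Cre, on chromosome 7. Itgam, Itgax and Cox6a2 beside it had 0.92 (SE 0.23), 0.38 (SE 0.13) and 2.48 (SE 0.61), while Pycard and Armc5 on either side had 0.022 (SE 0.16) and 0.099 (SE 0.24). These flanking genes and the span, 128062640 to 128206366, were chosen after the values were seen. Cox6a2, a cytochrome c oxidase subunit, was at 9.06 ± 6.17 CPM in cDC2 F/F and 56.98 ± 26.1 in cDC2 KO. Plcb1 had 5.05 (SE 0.81, adjusted p = 0.136), Plcb4 1.45 (SE 0.26, adjusted p = 0.228) and Fam149a 0.67 (SE 0.12). On the negative side were Stxbp6 -1.56 (SE 0.34, adjusted p = 0.474), Cela1 -4.19 (SE 0.92), Muc13 -4.19 (SE 0.94), Il1rn -1.07 (SE 0.25) and Car2 -1.27 (SE 0.303). Slc40a1 had -3.08 (SE 0.75) and fell when adjusted over the 30 iron handling genes alone (adjusted p = 0.0308), as did Il1rn over 30 cytokine genes, while Itgam rose and Clec4a2 fell over 25 cDC2 core genes. The averages of Slc40a1 and Clec4a2 rest mainly on cDC1, where they had -5.51 and -2.67. In cDC2 Slc40a1 ran from 0.0996 to 3.77 CPM in F/F and from 0.873 to 1.74 in KO (2-sided exact permutation p = 0.571). Clec4e rose over 26 pattern recognition genes and over 16 neutrophil markers, and Cox6a2 over 18 plasmacytoid DC markers.

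By edgeR 0 genes passed in the averaged comparison, with 813 at an unadjusted p under 0.05. Limma-voom called 3 (Itgad, Plcb1 and Ehf) and DESeq2 128 (18 higher, 110 lower). Leaving out 1 library gave 1 call in 5 cases: Itgad (2.08, adjusted p = 0.00521) without cDC1 F/F replicate 1, Clec4a2 without cDC1 F/F replicate 2, Ehf without cDC1 KO replicate 3, Ighv1-12 without cDC2 KO replicate 1 and Chchd6 without cDC2 KO replicate 2.

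All 27 epithelial markers had negative averaged log2 fold changes (median -2.49, camera adjusted p = 4.07e-17, and adjusted p = 0.0537 with an estimated correlation), and 13 fell over the list alone. The median was -0.49 without cDC1 F/F replicates 1 and 3. Macrophage markers had a median of -0.39 (adjusted p = 0.00156, and adjusted p = 0.438 with an estimated correlation). This was lost without cDC1 F/F replicate 1 or cDC2 KO replicate 2 (median -0.47 to -0.26) and without cDC1 F/F replicates 1 and 3 (-0.12). Cholesterol synthesis had a median of -0.197 (adjusted p = 3.34e-04, and adjusted p = 0.511 with an estimated correlation), with Msmo1 -0.43 (SE 0.17) and Fdft1 -0.68 (SE 0.31). Its median was -0.2999 without cDC2 KO replicate 1. Neutrophil markers had 1.14 (adjusted p = 2.12e-04, and adjusted p = 0.0537 with an estimated correlation), with Clec4e, a pattern recognition lectin, at 2.17. This median was 0.28 without cDC1 KO replicate 2, 0.65 without cDC1 KO replicate 3, 0.32 without cDC2 KO replicate 2 and 1.94 without cDC1 F/F replicates 1 and 3. In cDC1 the whole neutrophil list summed to only 9.59 ± 1.17 CPM in F/F and 10.7 ± 5.02 in KO, so the median rests on low levels there. Ribosomal protein genes had 0.16 (adjusted p = 1.56e-05, and adjusted p = 0.7799 with an estimated correlation). Oxidative phosphorylation genes had 0.12 (adjusted p = 8.85e-05, and adjusted p = 0.7799 with an estimated correlation). Both were lost without cDC2 KO replicate 1 (medians 0.00900 and 0.0102) and higher without cDC2 KO replicate 2 (0.25 and 0.22) and without cDC1 F/F replicates 1 and 3 (0.25 and 0.23). The latter was also 0.19 without cDC1 F/F replicate 1, 0.068 without cDC1 F/F replicate 2 and 0.076 without cDC2 F/F replicate 4.

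**Figure D4:**
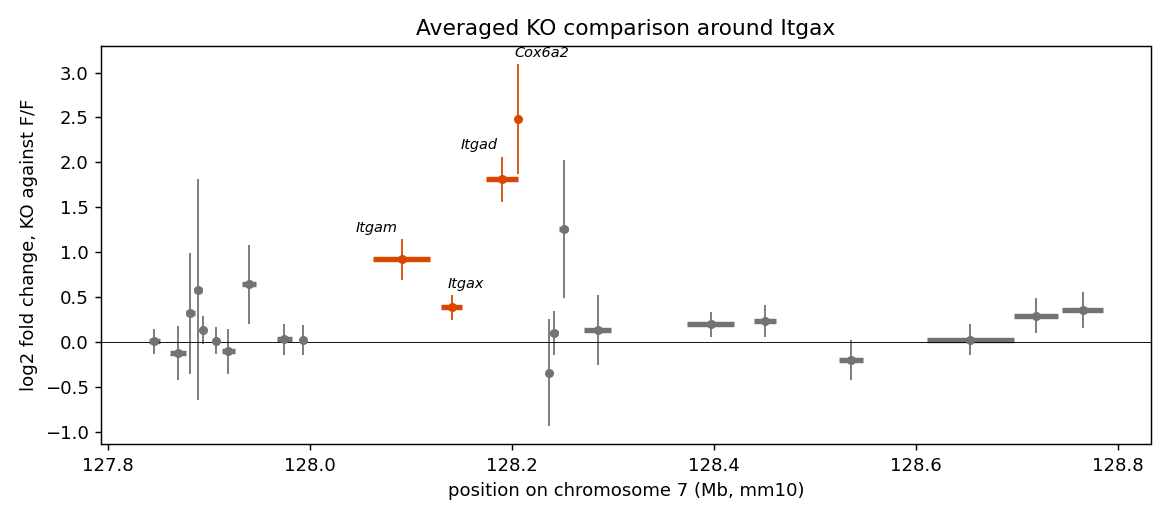
Averaged KO comparison for tested genes around Itgax on chromosome 7, with SE bars. Itgad has 1.81 (SE 0.25) and Cox6a2 2.48 (SE 0.61). The 10 tested genes on each side have a median of 0.11.

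The genotype effects of cDC2 and cDC1 were then compared. The difference was 2.003 (SE 0.42, adjusted p = 0.634) for Slc16a13, a monocarboxylate transporter. Emilin2, an extracellular matrix glycoprotein, had 2.58 (SE 0.58, adjusted p = 0.715), the membrane protease St14 2.03 (SE 0.51) and Fam160b2 1.61 (SE 0.41), and Zfp84 had -1.25 (SE 0.28, adjusted p = 0.715). Areg had 2.26 (SE 0.62, adjusted p = 0.792) and Clec4a2 2.52 (SE 0.67, adjusted p = 0.792). The Clec4a2 difference passed when adjusted over the 25 cDC2 core genes alone. Clec4a2 had -2.67 in cDC1 and -1.41 in the average, so its positive difference reflects the fall in cDC1 and no rise in cDC2. Over other lists alone, positive differences passed for Areg (-1.72 in cDC1) among 15 NK and ILC markers and for both erythroid genes. They also passed for 2 of 18 plasmacytoid DC markers, Klk1 and Atp1b1, which had -5.20 and -4.32 in cDC1. Areg was at 36.8 ± 7.11 CPM in cDC2 F/F and 53.5 ± 13.3 in cDC2 KO. Iron-sulfur and heme synthesis genes were negative in 20 of 24 (median -0.27, camera adjusted p = 0.00865, and adjusted p = 0.4802 with an estimated correlation). Among them is Alad, a heme synthesis enzyme, -0.93 (SE 0.47). Without cDC2 KO replicate 1 this call ended (median -0.42 to -0.15 over the left-out libraries). Cell cycle genes had a median of -0.49 (adjusted p = 0.00397, and adjusted p = 0.503 with an estimated correlation), lost without cDC1 KO replicate 2 (-0.62 to -0.33). MHC class II genes had a median of -0.27 (adjusted p = 0.0445, and adjusted p = 0.744 with an estimated correlation). This was lost without cDC1 F/F replicate 3, cDC1 KO replicate 2, cDC2 F/F replicate 4 or 5 or cDC2 KO replicate 1 (-0.74 to -0.069), and with the mitochondrial rRNA share as a covariate (-0.23, adjusted p = 0.215). By edgeR 0 genes passed, with 815 at an unadjusted p under 0.05. Limma-voom called 0 and DESeq2 66 (39 higher, 27 lower). Leaving out 1 library gave 1 call in 3 cases: Ehf without cDC1 KO replicate 3, Ighv1-12 without cDC2 KO replicate 1 and Chchd6 without cDC2 KO replicate 2.

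Marker lists of other cells passed camera for this difference too. B and plasma cell markers had a median of -2.05 (camera adjusted p = 7.32e-10, and adjusted p = 0.111 with an estimated correlation), negative in 20 of 21, and of -3.901 without cDC2 KO replicate 1. T cell markers, negative in 15 of 19, had a median of -1.23 (adjusted p = 0.00102, and adjusted p = 0.4802 with an estimated correlation). Epithelial markers were positive in 23 of 27 (median 2.16, adjusted p = 8.17e-05, and adjusted p = 0.4802 with an estimated correlation). This was lost without cDC2 KO replicate 2 (median 0.72), at 1.13 without cDC1 F/F replicate 3 and at -0.78 without cDC1 F/F replicates 1 and 3. The erythroid list (median 9.75, adjusted p = 0.00229, and adjusted p = 0.254 with an estimated correlation) rests on 2 genes. Hbb-b1 has 3 counts or fewer per group in cDC1 of both genotypes, so the fitted median is no estimate of size. It was lost without cDC1 F/F replicate 3 (median 6.95 to 11.1 over the left-out libraries).

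In F/F, cDC2 (5 libraries) were compared with cDC1 (3). Of the 25 cDC1 core genes 24 fell in cDC2, 0 rose and 1 did not pass. Their median was -3.14 (adjusted p = 1.33e-55, and adjusted p = 4.89e-04 with an estimated correlation). Clec9a, a receptor for dead cells, was at -4.04 (SE 0.29), the endosomal RNA sensor Tlr3 at -3.76 (SE 0.35), Plpp1 at -6.29 (SE 0.38) and the lysosomal thioesterase Ppt1 at -4.53 (SE 0.32). Of the 25 cDC2 core genes 20 rose and 1 fell. Their median was 5.09 (adjusted p = 8.39e-54, and adjusted p = 6.07e-05 with an estimated correlation). Cd209a rose by 9.16 (SE 0.54), Csf1r, the receptor for macrophage colony-stimulating factor, by 7.61 (SE 0.69), Tmem176a by 5.51 (SE 0.31), Tmem176b by 5.598 (SE 0.35) and Cd7 by 5.09 (SE 0.28). Among the largest rises with no overlap were Fcrls 9.86 (SE 1.04), Retnla, a resistin-like secreted protein, 9.55 (SE 1.096), Gm9733 9.51 (SE 0.299), Npl 9.29 (SE 1.01) and Clec4e 8.998 (SE 0.95). Among the largest falls were Ctla2b -7.36 (SE 0.52), the prostacyclin synthase Ptgis -6.73 (SE 0.83), the sterol hydroxylase Cyp8b1 -6.53 (SE 0.902) and Gpr141b -6.37 (SE 0.33).

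Inflammatory cytokine genes rose in 17 and fell in 2 of 30. Their median was 1.72 (adjusted p = 6.23e-05, and adjusted p = 0.0651 with an estimated correlation). Il1rn rose by 3.48 (SE 0.36), the chemokine Ccl9 by 6.54 (SE 0.68) and the prostaglandin synthase Ptgs2 by 5.103 (SE 0.56), while Il12b, a subunit of interleukins 12 and 23, fell by 4.93 (SE 0.44). Interferon-stimulated genes rose in 17 and fell in 4 of 34 (median 1.17, adjusted p = 8.08e-06, and adjusted p = 0.217 with an estimated correlation). Rtp4 rose by 5.53 (SE 0.51), the RNA sensor Ddx58 (RIG-I) by 4.88 (SE 0.48) and Oasl2 by 2.87 (SE 0.34). Pattern recognition genes rose in 11 and fell in 3 of 26 (median 0.81, adjusted p = 0.010001, and adjusted p = 0.0651 with an estimated correlation), a call that ended without cDC1 F/F replicates 1 and 3 (median 1.38, adjusted p = 0.0703). The 3 that fell were Tlr3, Tlr11 at -4.12 (SE 0.405) and Tlr12 at -4.07 (SE 0.42). MHC class I presentation genes fell in 10 of 20, and 0 rose. Their median was -0.65 (adjusted p = 1.88e-04, and adjusted p = 0.183 with an estimated correlation). The immunoproteasome subunit Psmb9 was at -1.27 (SE 0.16), the peptide transporter Tap2 at -1.17 (SE 0.21) and the chaperone Pdia3 at -1.61 (SE 0.24). Maturation and migration genes went both ways, 8 up and 6 down of 29 (median -0.066, adjusted p = 0.8603), Socs2 rising by 2.13 (SE 0.32) and Apol7c at -2.95 (SE 0.45). Mucosal tolerance genes did too, 4 up and 3 down of 22 (median 0.082, adjusted p = 0.886), with Il22ra2, a decoy receptor for interleukin 22, at 5.57 (SE 1.03) and Itgae (CD103) at -1.46 (SE 0.17). MHC class II genes rose in 2 and fell in 6 of 13 (median -0.64, adjusted p = 0.282). Ribosomal protein genes rose in 11 and fell in 1 of 81 (median 0.46, adjusted p = 3.26e-04, and adjusted p = 0.684 with an estimated correlation).

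Iron handling genes rose in 7 and fell in 1 of 30 in F/F cDC2 against cDC1, and over the list alone 8 rose and 3 fell (median 0.17, adjusted p = 0.112). Fth1, the ferritin heavy chain, rose by 1.38 (SE 0.22, adjusted p = 5.30e-04), the heme exporter Flvcr1 by 2.12 (SE 0.27), the hemoglobin scavenger receptor Cd163 by 5.65 (SE 0.75) and the metal importer Slc39a14 by 3.14 (SE 0.42). Ftl1 had -0.53 (SE 0.21, adjusted p = 0.0914) and Tfrc 0.48 (SE 0.202, adjusted p = 0.115). Of 20 hepcidin-inducing signal genes 5 rose and 1 fell (median 0.43, adjusted p = 0.0879): Id3, a target of bone morphogenetic proteins, by 3.73 (SE 0.602), Smad7 by 1.69 (SE 0.28), Smad4 by 1.12 (SE 0.202) and Id2 at -0.89 (SE 0.19).

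Macrophage and monocyte markers rose in 19 of 24 in F/F cDC2 (median 4.56, adjusted p = 1.13e-17, and adjusted p = 4.89e-04 with an estimated correlation). C1qa was at 5.84 (SE 0.601), C1qb at 6.83 (SE 0.72) and C1qc at 5.85 (SE 0.51). The list's sum was 3967 ± 817 CPM in cDC1 F/F and 7849 ± 1768 in cDC2 F/F. T cell markers rose in 14 of 19 (median 2.35, adjusted p = 6.06e-08, and adjusted p = 0.0981 with an estimated correlation). Il7r was at 4.39 (SE 0.34) and Cd8b1 at 6.57 (SE 0.803). B and plasma cell markers rose in 11 and fell in 1 of 21 (median 3.52, adjusted p = 6.23e-05, and adjusted p = 0.101 with an estimated correlation), with Jchain at 6.72 (SE 1.44) and Ighm at -1.27 (SE 0.21). NK and ILC markers rose in 4 of 15 (median 1.98, adjusted p = 0.00646, and adjusted p = 0.102 with an estimated correlation), with Nkg7 at 4.14 (SE 0.63). Neutrophil markers rose in 5 of 16 (median 4.08, adjusted p = 0.00705, and adjusted p = 0.0817 with an estimated correlation), with Trem1 at 7.76 (SE 1.11). Plasmacytoid DC markers rose in 8 and fell in 1 of 18 (median 0.76, adjusted p = 6.77e-06, and adjusted p = 0.0651 with an estimated correlation), with Lair1 at 3.67 (SE 0.25). Their median was 1.303 without cDC1 F/F replicate 1 and 1.68 without cDC1 F/F replicate 3, and 2.95 (adjusted p = 9.04e-08) without both. The sums were 35.1 ± 5.66 and 216 ± 56.5 CPM for T cells and 522 ± 48.4 and 8435 ± 4924 for B and plasma cells in cDC1 and cDC2 F/F.

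By edgeR 3030 genes changed between the F/F subsets (1594 higher and 1436 lower in cDC2), 2108 of them by over 2-fold, with 5189 at an unadjusted p under 0.05. Limma-voom called 3510 and DESeq2 4275, and groups did not overlap in 25.1% of genes where chance gives 3.57%. The count was 1880 without cDC1 F/F replicate 2, and 1169 without cDC1 F/F replicates 1 and 3. Of the proteins the sort used, Xcr1 fell from 1077 ± 178 to 13.01 ± 4.76 CPM and Sirpa (CD172a) rose from 0.778 ± 0.756 to 188 ± 25.6. Itgax had 0.71 (SE 0.17), Adgre1 (F4/80) 1.31 (SE 0.31) and Fcgr1 (CD64) 5.45 (SE 1.13).

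In KO, cDC2 (2 libraries) were compared with cDC1 (3). Of the cDC1 core genes 23 of 25 fell (median -2.899, adjusted p = 1.02e-35, and adjusted p = 6.57e-04 with an estimated correlation). Cadm1, an adhesion molecule, was at -5.77 (SE 0.596), Plpp1 at -8.096 (SE 0.62) and Ppt1 at -4.77 (SE 0.48). Of the cDC2 core genes 21 rose and 1 fell (median 4.74, adjusted p = 1.72e-48, and adjusted p = 6.57e-04 with an estimated correlation). Clec4a4 was at 9.74 (SE 0.87), Clec4a2 at 9.298 (SE 0.61), S100a4 at 7.997 (SE 0.49) and Cd209a at 9.02 (SE 0.56). Retnla rose by 10.38 (SE 1.16) and the matrix protein Fn1 (fibronectin) by 9.53 (SE 1.33), while Ctla2b was at -7.78 (SE 0.81), Ptgis at -9.48 (SE 1.502) and Ttc39a at -6.53 (SE 0.97). Inflammatory cytokine genes rose in 12 and fell in 2 of 30 (median 1.496, adjusted p = 6.38e-05, and adjusted p = 0.0503 with an estimated correlation). Osm rose by 4.69 (SE 0.43), Ccl9 by 7.55 (SE 0.75) and Ptgs2 by 5.38 (SE 0.604). Pattern recognition genes rose in 12 and fell in 3 of 26 (median 1.26, adjusted p = 0.00717, and adjusted p = 0.0503 with an estimated correlation), with the inflammasome sensor Nlrp3 at 2.37 (SE 0.27) and Tlr12 at -4.71 (SE 0.63). Interferon-stimulated genes rose in 13 and fell in 1 of 34 (median 0.95, adjusted p = 3.32e-04, and adjusted p = 0.312 with an estimated correlation), Ddx58 by 6.43 (SE 0.56). MHC class I genes fell in 4 of 20 (median -0.53, adjusted p = 0.00267, and adjusted p = 0.312 with an estimated correlation), with Psmb9 at -1.29 (SE 0.21). Maturation genes rose in 6 and fell in 5 of 29 (adjusted p = 0.713). Tolerance genes rose in 5 and fell in 2 of 22 (adjusted p = 0.342), with Areg at 3.44 (SE 0.505) and the matrix protein Thbs1 at 4.47 (SE 0.88). Unfolded protein response genes rose in 1 and fell in 6 of 21 (median -0.72, adjusted p = 0.00958, and adjusted p = 0.351 with an estimated correlation), with a median of -0.44 without cDC1 KO replicate 3 and -0.44 without cDC2 KO replicate 1. Ribosomal protein genes rose in 18 and fell in 1 of 81 (median 0.57, adjusted p = 1.56e-04, and adjusted p = 0.647 with an estimated correlation). MHC class II genes rose in 2 and fell in 6 of 13 (median -0.84, adjusted p = 0.0332, and adjusted p = 0.577 with an estimated correlation). Iron-sulfur and heme synthesis genes fell in 3 of 24 (median -0.49, adjusted p = 0.0249, and adjusted p = 0.312 with an estimated correlation). Both of these calls ended without cDC2 KO replicate 1, and the class II median was -0.46 without it and -1.38 without cDC2 KO replicate 2. With the mitochondrial rRNA share as a covariate the class II, iron-sulfur and unfolded protein response calls ended (medians -0.5, -0.37 and -0.32, adjusted p = 0.114, 0.0513 and 0.0733).

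Iron handling genes rose in 7 and fell in 3 of 30 between the KO subsets (list alone 10 and 3; median 0.069, adjusted p = 0.222), Fth1 by 1.12 (SE 0.26, adjusted p = 0.00853) and Flvcr1 by 2.69 (SE 0.31). Slc40a1, at 0.0428 ± 0.00152 CPM in cDC1 KO and 1.31 ± 0.616 in cDC2 KO, rose by 4.85 (SE 1.12, adjusted p = 0.00872), a fitted size that rests on 2 counts in each cDC1 library, and Ftl1 fell by 1.21 (SE 0.27, adjusted p = 0.00777). Both calls ended without cDC2 KO replicate 1. Hepcidin-inducing signal genes rose in 6 and fell in 1 of 20 (adjusted p = 0.107), with Id3 at 4.88 (SE 0.69) and Bmp2, a bone morphogenetic protein, at 4.51 (SE 1.02). Macrophage markers rose in 16 of 24 (median 4.65, adjusted p = 3.44e-15, and adjusted p = 0.005801 with an estimated correlation), Csf1r by 8.13 (SE 0.74) and C1qc by 6.85 (SE 0.56). Plasmacytoid DC markers rose in 10 of 18 (median 2.89, adjusted p = 7.13e-08, and adjusted p = 0.0409 with an estimated correlation), with Siglech at 3.12 (SE 0.52). T cell markers rose in 4 of 19 (median 1.03, adjusted p = 0.00344, and adjusted p = 0.312 with an estimated correlation) and NK and ILC markers in 5 of 15 (median 2.51, adjusted p = 0.00621, and adjusted p = 0.0882 with an estimated correlation), the latter with a median of 1.44 without cDC2 KO replicate 1 and 1.65 without cDC2 KO replicate 2. Neutrophil markers rose in 7 of 16 (median 4.71, adjusted p = 1.90e-04, and adjusted p = 0.0503 with an estimated correlation), while B and plasma cell markers rose in 2 and fell in 2 of 21 (adjusted p = 0.5196). By edgeR 2859 genes changed (1642 higher, 1217 lower in cDC2), 2311 by over 2-fold, with 5036 at an unadjusted p under 0.05. Limma-voom called 2610 and DESeq2 4213, groups did not overlap in 48.2% of genes where chance gives 20%, and the count was 1217 without cDC2 KO replicate 1 and 1832 without cDC1 KO replicate 2.

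Of the genes called between subsets, 2002 were called in both genotypes, 2000 of them in the same direction: 1136 higher and 864 lower in cDC2, where 165 and 110 would be shared if the calls were independent. Of the 3030 F/F calls 97.6% had the same sign in KO, and log2 fold changes correlated across all 15899 genes with r = 0.56. The genotypes share no library. Both comparisons rest on the same sorting gate and on 1 fit with a shared estimate of the spread. Overlap above the number for independent calls was therefore bound to follow and is no separate test.

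**Figure D5:**
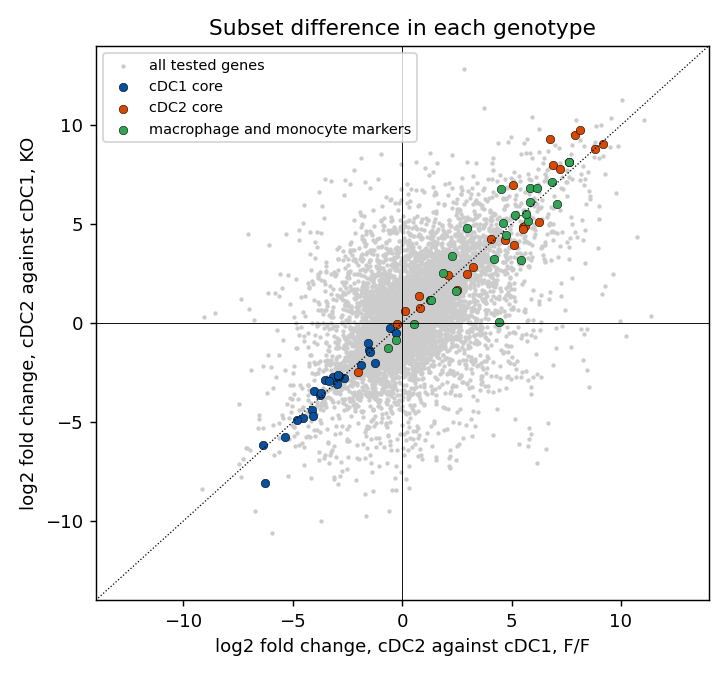
cDC2 against cDC1 log2 fold change in F/F and in KO for each tested gene. Of 3030 genes called in F/F and 2859 in KO, 2002 are called in both, and r = 0.56 over 15899 genes.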

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

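Of the tests below, the second epithelial gene set and the liver gene set were chosen before their results were seen; the other cell lists, the ratios of Slc40a1 and Ehf, the permutation of the epithelial sum, the tests around Itgax, the macrophage markers of low level, the macrophage rank of the Hamp library, the mitochondrial rRNA of the splits, the splits of the libraries and the fits without cDC1 F/F replicates 1 and 3 or with mitochondrial rRNA were chosen only after the results were seen.

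Single cDC2 F/F libraries stood far from the other 4 in 9 of 159 values tested, where about 1 in 20, or 7.95, would by chance. Hamp was at 10.04 CPM in replicate 3 against 0 to 0.25 in the others, Gpr141b at 10.5 and Ly6c2 at 132 in replicate 3 and Cela1 at 16.9 in replicate 2. Fam149a stood at 5.50 CPM in replicate 2, Cyp8b1 at 0.768 and Ttc39a at 11.8 in replicate 1, Ppt1 at 399 and Hbb-b1 at 0.364 in replicate 5.

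The genotype effect differed between cDC2 and cDC1 by camera in 7 lists, as median log2 differences: iron-sulfur and heme synthesis -0.27, MHC class II -0.27, cell cycle -0.49, B and plasma cell markers -2.05, T cell markers -1.23, epithelial markers 2.16 and erythroid markers 9.75, the last resting on Hbb-b1 at 3 counts or fewer per group in cDC1. With an estimated correlation 0 of these lists passed by camera, and by the directional test of fry 0 did. By edgeR 0 single genes passed for this difference, with 815 at an unadjusted p under 0.05, and limma-voom called 0 and DESeq2 66.

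Epithelial transcripts, Slc40a1 and Ehf were lower in KO than in F/F cDC1 libraries. A second set of epithelial genes, none in the first list, had a median log2 fold change of -3.14 in cDC1 (27 of 30 negative) and -0.28 in cDC2 (19 negative), so epithelial cells or their RNA in the F/F libraries are a candidate source of the marker difference in cDC1, although the gate requires CD45 and MHCII. A lower share of all other cells in the KO libraries would lower their markers too. The T cell, NK and ILC, stromal, endothelial and mast cell lists, 70 genes, had a median of 0.11 (quartiles -0.41 to 0.71). This argues against a lower share of those cells only. At most 2 members of each list reached 10 CPM in every cDC1 library, and the macrophage list, not among them, had a median of -0.36. An epithelial source of Slc40a1 and of Ehf cannot be told apart from other sources. Their ratios of F/F replicate 2 to replicates 1 and 3, 0.475 and 0.91, lie above 81.5% and 85.2% of the epithelial markers, but the markers' 95th percentile of 3.54 also admits a gene that does not follow them. F/F replicate 2 kept 1.19 CPM of Slc40a1 and 6.49 of Ehf against means of 0.0428 and 0.204 in KO. With replicate 2 as the only cDC1 F/F library, the epithelial median was -0.41. The epithelial sum of replicate 2, 169 CPM, still lay above the 72.7 to 81.2 of the KO libraries. This 1 library, not free of epithelial transcripts, therefore does not decide against that source. In cDC2 F/F replicate 2, a single library, the epithelial sum was the highest of its group, 748.5 CPM, and Slc40a1 the lowest, 0.0996 CPM. Its mean log2 CPM (plus 1) over the epithelial list, 2.32, was below the 2.43, 2.34 and 2.54 of replicates 3, 4 and 5. Whether that library goes against an epithelial source thus depends on the measure. Lower epithelial transcripts as an effect of the KO genotype in both subsets cannot be told apart from uneven carry-over with so few libraries. F/F replicate 2, at 169 CPM against 540 and 866 in replicates 1 and 3, shows that the sum varies within a genotype. The exact permutation does not decide this: its adjusted p = 0.0786 is the smallest raw p of 420 arrangements (0.00238) times 33 lists, so the list could not have passed alone.

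Itgam, Itgax, Itgad and Cox6a2, side by side on chromosome 7, had positive averaged log2 fold changes in KO, and 0 passed (adjusted p = 0.583, 0.839, 0.0648 and 0.583). Of these, Itgad had each KO library above each F/F library in both subsets, and the others did not. Over all tested genes 22 did so, where chance gives 37.9, so this separation alone is no evidence for an effect. In cDC1, 15 macrophage and monocyte markers below the F/F level of Itgad had a median of -0.66 (11 negative, upper quartile 0.11) where Itgad had 2.08. These values argue against such cells in the KO libraries, but with limits. F/F replicate 1 had the highest mean log2 CPM (plus 1) over the whole list among the cDC1 libraries, 3.25. Without it the median of the whole list was -0.024, and the 15 markers were not examined without it. Ly6c2 had 4.04 (SE 1.202), from 117 CPM in KO replicate 3. In cDC2 macrophages or monocytes cannot be told apart from other sources, since 4 such markers (median 0.073) are too few and the others have a high baseline, although the gate excludes F4/80 and CD64. Extra copies of the Itgax region carried by the CD11c-Cre transgene and loss of Hamp cannot be told apart, because 0 libraries carry the transgene with an intact Hamp gene and the genes it carries are not given in the sources used here. The 10 tested genes on each side, with a median of 0.11, do not go against extra copies and do not show them.

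Hamp was detected well above the floor in 1 cDC2 F/F library. Liver cell RNA is argued against: the liver gene set in that library was at 0.996 times the highest of the other cDC2 F/F libraries, with 1 count of Alb. Macrophages or monocytes in that library cannot be told apart from other sources: it ranks 4 of the 5 cDC2 F/F libraries in macrophage marker CPM from the highest, but sums of 5949 to 10226 CPM would hide a small share. The gate excludes F4/80 and CD64, but the monocyte marker Ly6c2 stood at 132 CPM there against 23.5 to 43.6 in the others. Among the 5 libraries it also had the highest sums of B and plasma cell (13796 CPM), T cell (285) and plasmacytoid DC markers (826). The next highest were close, at 12734, 270 and 787, and marker lists of the other cell types were not highest there. What sets the library apart stays open. Beyond RNA of liver cells and of macrophages or monocytes no explanation was tested, and the design gives no biological one for a single library.

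For KO against F/F in cDC1, 2 of the 10 splits of the 6 libraries gave as many genes as the real one (real 1, highest other 5), and 10 splits are too few for a share under 0.05. For the averaged comparison the real split called 0 genes by edgeR (813 at an unadjusted p under 0.05; limma-voom 3, DESeq2 128), so 100 of 100 drawn splits of 420 had to give at least as many and do not tell whether chance is excluded. The highest other split called 86 and the rest at most 1. This single draw sets cDC1 F/F replicates 1 and 2, cDC1 KO replicate 1, cDC2 F/F replicate 2 and cDC2 KO replicate 1 apart. Of the 100 splits it has the largest difference in mitochondrial rRNA share (log2 1.31, against 0.026 in the real one), which points to a structure of the libraries other than genotype, but the split with the next largest called 0, so its nature stays open. For cDC2 against cDC1 in F/F, 1 of 56 splits, the real one, gave 3030 genes and the highest other 4. Each other split mixes sorted cDC1 and cDC2 libraries within a group, which widens the spread, so few calls were bound to follow there. These splits therefore do not tell whether chance is excluded.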

How the results depend on the processing

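The fits without cDC1 F/F replicates 1 and 3 and with the mitochondrial rRNA share as a covariate were chosen after seeing the data; the cause of a difference was not tested unless stated. Counts of changed genes, in the order cDC1 KO, cDC2 KO, average, difference of effects, F/F subsets and KO subsets, were 1, 1, 0, 0, 3030 and 2859. With no filter (25413 genes) the first 3 were 2, 7 and 3; with DESeq2 the first 4 were 113, 128, 128 and 66; with limma-voom cDC2 KO gave 0 and the average 3. With only the libraries compared, cDC1 KO and cDC2 KO gave 0 and 0, where fewer libraries set the spread. A block by the title's replicate number, which leaves 3 residual degrees of freedom instead of 9, gave 0 and 0 for these and 1574 for the KO subsets, and a block by the number in the description gave 1693. Without cDC1 F/F replicates 1 and 3 cDC1 KO gave 0 and the F/F subsets 1169; with mitochondrial rRNA as covariate cDC1 KO gave 0, cDC2 KO 2, and 5 lists passed in cDC1 KO, 4 of them in the main fit. That covariate ended the list calls of iron-sulfur and heme synthesis, unfolded protein response, cell cycle and macrophage markers in cDC1 KO, stromal markers in cDC2 KO, MHC class II in the difference of effects, and iron-sulfur, MHC class II and unfolded protein response in the KO subsets. It added ribosomal proteins in cDC1 KO, oxidative phosphorylation in the difference and erythroid markers in the KO subsets. Without cDC1 F/F replicates 1 and 3 the epithelial call in cDC1 KO ended with a smaller median (-3.38 to -0.41), as did macrophage markers in the average (-0.39 to -0.12) and erythroid markers in the difference (9.75 to 7.41). The calls of iron-sulfur (0.13 to 0.21) and cell cycle (0.12 to 0.32) in cDC1 KO, MHC class II in the difference (-0.27 to -0.28) and pattern recognition in the F/F subsets (0.81 to 1.38) ended with medians as large or larger, so these losses do not show that the shifts came from the 2 libraries. Lists called with an estimated correlation were 0, 0, 0, 0, 3 and 4, and with fry 0, 0, 0 and 0 for the first 4. Calls by fry are by its directional p, and its mixed p, for changes both ways, is not given here. Leaving out 1 library at a time, the counts ran from 0 to 5, 1 to 7, 0 to 1, 0 to 1, 1880 to 2978 and 1217 to 2864, the lists called from 5 to 9, 6 to 14, 5 to 8, 5 to 13, 14 to 15 and 15 to 15, and the mean Hamp level in cDC2 F/F from 0.124 to 2.63 CPM; without a cDC2 KO library the lone one is assumed to vary like the other groups. The direction turned in the following lists, with medians given as the lowest and highest over the left-out libraries. In cDC1 KO these were the cDC2 core list (-0.299 to 0.18, the highest without F/F replicate 1, and 0.43 without F/F replicates 1 and 3) and the test's direction for macrophage markers (-0.42 to -0.024, the last without F/F replicate 1, and -0.039 without both), and the unfolded protein response at -0.11 without both. In cDC2 KO ribosomal proteins (-0.049 to 0.42) turned without KO replicate 1, and for the cDC1 core list (main 0.039) the median turned without KO replicate 2 (-0.57) and the test's direction without KO replicate 1 (0.51). That list also turned in the average (-0.24 to 0.17, the lowest without cDC2 KO replicate 2), in the difference of effects its median turned without cDC2 KO replicate 2 (-0.56) and the test's direction without cDC2 KO replicate 1 (0.38), and epithelial markers in that difference were at -0.78 without cDC1 F/F replicates 1 and 3. Of 7943 alternatives for 470 values of named genes, 7706 kept their side of the threshold, 149 lost and 88 gained a call. Among values called in the main fit or in the alternative, 0 turned in sign. Sign changes of values called in neither were not counted. Most of the 470 values were not called at all: of the 174 past the threshold, 120 stayed past it under every alternative. Equal replicate numbers did not mark closer libraries throughout: of 3, 2, 3 and 2 pairs by title number (F/F subsets, KO subsets, cDC1 genotypes, cDC2 genotypes) 2, 2, 2 and 1 were closest to their own number, with r from -0.11 to 0.12. Pairs across genotypes cannot be 1 animal. By description number 2 of 3 pairs of the F/F subsets and 2 of 2 of the KO subsets were closest (r from -0.036 to 0.12). So few pairs neither show nor exclude a pairing of subsets by animal. The library with prefix M is cDC2 F/F replicate 5. Depth limits transcripts near 3 counts per library, such as Slc40a1 in cDC1 KO.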

Other observations

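Glycolysis and hypoxia genes rose in 4 and fell in 4 of 28 between F/F subsets (median -0.18, adjusted p = 0.895), lysosome and cathepsin genes rose in 7 and fell in 6 of 24 (0.17, 0.6901), and immediate early and dissociation genes rose in 2 and fell in 6 of 27 (-0.29, 0.159). In KO these were 5 and 3 of 28 (-0.0296, adjusted p = 0.767), 4 and 7 of 24 (-0.26, 0.252) and 3 and 8 of 27 (-0.071, 0.146). Cholesterol synthesis genes rose in 2 and fell in 4 of 21 between F/F subsets (-0.51, adjusted p = 0.0519) and cell cycle genes rose in 2 of 36 (0.37, 0.112). Mast cell, basophil and eosinophil markers rose in 3 of 8 in F/F cDC2 (2.24, adjusted p = 0.0879), stromal markers in 3 of 19 (1.76, 0.0879), and endothelial markers rose in 2 and fell in 2 of 9 (1.17, 0.372). Each of the sex-linked and mitochondrial-encoded lists had 2 tested members, with medians of 0.504 (adjusted p = 0.886) and 0.74 (0.838).

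Plcb1 (chromosome 2, 134786164 to 135475258) and Plcb4 (135658603 to 136014602) are neighbours, a relation looked up after their values were seen. In the averaged KO comparison they had 5.05 (SE 0.81) and 1.45 (SE 0.26), while Tmx4 and Mkks on either side had -0.37 (SE 0.21) and 0.0013 (SE 0.17).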
